A study of Arabidopsis thaliana with 4 samples.

How the data were processed

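Total RNA from root tips of Arabidopsis thaliana was measured on 4 Agilent 2-colour arrays. Per the labels, seedlings grew on nutrient agar at 23 °C with 16 h of light and 8 h of dark, and RNA was taken with a plant RNA kit from about 1 cm of the root tip. Each array carried RNA of 1 mutant line in one dye and RNA of wild-type Col-0 in the other. The line labelled ago1-101 was on 2 arrays and the line labelled scr-3 on 2, and in each pair the dyes were exchanged between the arrays. Groups were taken from the source labels of the mutant channel. The labels give no replicate numbers, so the arrays of a pair were numbered in the order of deposition. The fit did not pair arrays by these numbers. Arrays of the same number were set against each other to compare channels between the pairs and to check the sign of genes named for the difference.

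The deposited scanner files hold spot intensities (mean signal and median local background per dye, neither corrected). Per the submitters' processing notes they were made with Agilent Feature Extraction 9.1.3.1. The same deposited files hold a log10 ratio of Cy5 over Cy3, made by the authors' software from background-subtracted, detrended and dye-normalised intensities, and a p-value of that ratio from the software's error model. The deposited series table holds the same log10 ratio, turned to mutant over Col-0 on the 2 arrays with the mutant in Cy3. The largest difference from the scanner files was 4.99e-06 over 39102 spots per array. The array name in the file headers showed that both arrays numbered 1 lay on 1 slide and both arrays numbered 2 on a second slide. The mutant was in Cy5 on the first slide and in Cy3 on the second.

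The main values were computed from the uncorrected intensities in R 4.3.3 with limma 3.58.1 and the package data.table, version 1.17.8. Background was removed by the normexp method with an offset of 50, and log2 ratios were normalised within each array by loess. Control spots had no weight in the loess and were left out afterwards. Spots called non-uniform or population outliers by Feature Extraction were left out, between 104 and 147 per array, and 0 spots were saturated. Spots of 1 probe were averaged, and each locus took its brightest probe over the 4 arrays (541 loci had more than 1 probe). A locus was tested where its probe lay well above background in the RNA of either mutant on both its arrays, or in Col-0 on all 4. Of 25665 loci on the array, 20025 were tested, 5412 were too dim, and 228 had no probe with a usable spot on all 4 arrays. The gene names came from the reference annotation for 8712 tested loci. The 216 loci absent from the annotation kept their identifiers. The genome build behind the array design is not named in the files, so no positions are given.

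All 4 arrays were fitted together in limma with a dye term and 1 effect per mutant, which left 1 residual degree of freedom. Empirical Bayes moderation added 4.51 prior degrees of freedom (prior SD 0.063 on the log2 scale). Because slide and dye orientation coincide, the dye term also takes up differences between the slides, and no separate slide block could be fitted. P-values were adjusted by the Benjamini-Hochberg method over the 20025 genes, with a threshold of 0.05. The contrasts were each mutant against Col-0, and the difference of the 2 effects (ago1-101 minus scr-3). As a count that needs no estimate of spread, genes at least 2-fold changed in the same direction on both arrays of a pair were also counted. In results given below, the log2 fold change is the mean over the 2 arrays of a pair, with its SE from the fit and n = 2 arrays. That SE leaves out a shift between the arrays of a pair that both pairs share, which the dye term takes up.

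Gene lists, groups, the model, the list tests and the naming rule were fixed before the data were examined, as were the alternatives except those named as added. The 24 lists were targeted genes (AGO1 and SCR), SHORT-ROOT and SCARECROW pathway, microRNA targets, small RNA machinery, endodermis and Casparian strip, suberin, cortex and root triterpenes, xylem, phloem, pericycle and procambium, root hairs, epidermal patterning, root cap, stem cell niche, cell cycle, auxin response and transport, cytokinin response, phosphate starvation, iron and copper, defence, abscisic acid and drought, flavonoid synthesis, photosynthesis and shoot tissue, and reference genes. Lists with at least 3 tested members (23) were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the lists. At that preset the test treats genes as nearly independent units, so its p-values do not measure spread between plants or arrays. Members were counted over all genes tested and adjusted over the list alone. As alternatives, camera was run with an estimated correlation and fry was run. Camera with an estimated correlation rests on the 1 residual degree of freedom. Its lowest p without adjustment over all lists was 0.0785, so its adjusted p-values do not decide on any single list. Each list median was also ranked among the medians of 10000 random lists matched for brightness in 20 bins.

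The genes named for each mutant are AGO1 and SCR, then the 10 largest rises and the 10 largest falls among genes with a symbol, an adjusted p under the threshold and the same sign on both arrays, and up to 4 members of each list with the smallest p. For the difference, the 5 largest each way are named. A gene not well above background in one of the RNAs is given as a bound.

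The alternatives were the fit without the dye term, no background correction, the deposited log ratios, the series table, median centring in place of loess, scaling between arrays, no filter or a stricter filter on dim probes, the mean of all probes of a locus, an intensity trend in the prior, each mutant fitted alone, a fold threshold of 2 in addition, the software's own p-value under 0.01 on both arrays, and leaving out each array in turn. Lists without AGO1 and SCR, the targets of each microRNA under each scaling, the overlap of the pairs and the neighbouring genes under each scaling and without each array, fry on lists without AGO1 and SCR, and camera with an estimated correlation in the fit without the dye term, were added after the data were seen. The fit was tested on simulated data with 200 changed genes per mutant among 20025. The noise was drawn from the prior of the fit, with a dye effect common to all arrays, as the model assumes. The real data gave far more calls, 9651 and 11309, so the simulated shares do not carry over to them. All 50 genes changed 2-fold and all 50 changed 4-fold were recovered in each mutant, and of the 50 changed 1.5-fold, 49 and 50 were recovered. Of the 50 with the smallest simulated change, 26 and 38 were recovered. Calls on unchanged genes numbered 17 and 15, or 8.85% and 7.39% of all calls, above the share of 5% that the threshold allows.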

Results

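Root tips of 2 Arabidopsis mutants were compared with root tips of wild-type Col-0. AGO1 encodes ARGONAUTE1, the main effector protein of microRNA silencing. SCR encodes SCARECROW, a transcription factor needed for the division that forms endodermis and cortex and for the stem cell niche of the root. The line labelled ago1-101 carries a T-DNA insertion named on the label, and scr-3 is an allele of SCR. Each line was compared with Col-0 on 2 arrays with exchanged dyes (n = 2 arrays per pair). Each array held 37685 spots other than controls, with a median signal of 125.8 to 138.3 in Cy3 and 287.3 to 327.7 in Cy5. Between 63.5% and 66.1% of spots lay well above background per dye and array. The number of arrays limits the precision. The labels do not say whether the arrays of a pair used separate plants or extracts. The p-values therefore rest only on spread between these arrays, which may be technical. The dye term took up spread common to both pairs, so the SE and p-values leave that part out. Without the dye term, 5243 genes passed in place of 9651 in the pair labelled ago1-101. In the pair labelled scr-3, 6122 passed in place of 11309. Across the 20025 tested genes, which are not independent replicates, the log2 ratios of the 2 arrays had r = 0.904 in the pair labelled ago1-101 and r = 0.921 in the pair labelled scr-3.

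The genes the mutants are named for were each low in the pair that carries the other label. AGO1 (AT1G48410) was 50.6-fold lower than Col-0 in the pair labelled scr-3 (log2 fold change -5.66, SE 0.040, adjusted p = 6.8e-07), at -5.73 and -5.59 on its arrays. The log2 fold change was -6.38 with the deposited log ratios and -4.94 with scaling between arrays. In the pair labelled ago1-101, AGO1 was 1.15-fold lower (-0.21, SE 0.040, adjusted p = 0.0088), and this call ended without the dye term (adjusted p = 0.11). SCR (AT3G54220) was 4.81-fold lower in the pair labelled ago1-101 (-2.27, SE 0.043, adjusted p = 3.8e-06), at -2.46 and -2.07 on its arrays. In the pair labelled scr-3, SCR did not pass (-0.11, SE 0.043, adjusted p = 0.084). The differences between the pairs passed for both genes, at 5.45 (SE 0.057) for AGO1 and -2.16 for SCR. Where the AGO1 and SCR probes lie relative to the mutations is not known. The labels were kept as deposited, so every direction below belongs to the pair that carries the named label. The AGO1 and SCR values argue against these labels without excluding them, and an exchange of the labels is a candidate explanation.

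**Figure D1:**
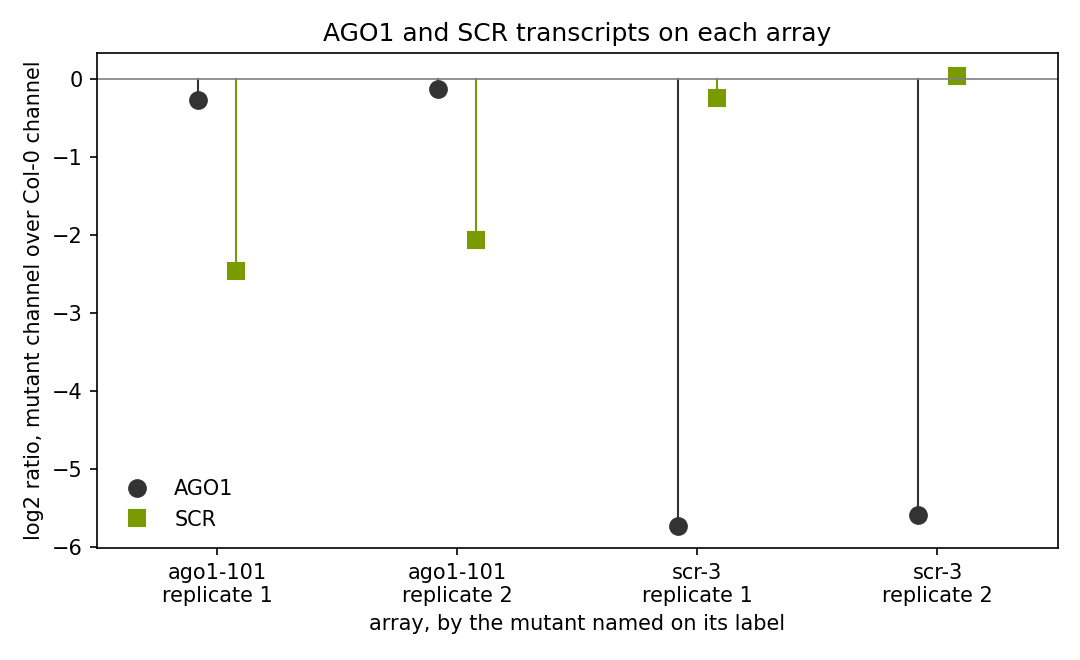
Log2 ratio of mutant over Col-0 for AGO1 and SCR on each of the 4 arrays, 1 point per array, named by the mutant on the label. AGO1 lies at -5.73 and -5.59 on the arrays labelled scr-3, and SCR at -2.46 and -2.07 on the arrays labelled ago1-101.

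The pair labelled ago1-101 was compared with Col-0 to find transcripts that differ in root tips of that line. The largest rise among genes with a symbol was in LAC12 (AT5G05390), a laccase, 32.1-fold higher (log2 5.01, SE 0.074), and the related LAC5 was 17.9-fold higher. BCB, a blue copper-binding protein, rose 31.7-fold, XTH20, an enzyme that remodels xyloglucan, 20.2-fold (log2 5.115 and 3.563 on its arrays), and the amino acid permease gene AAP3 13.4-fold. CYP86A1, the fatty acid hydroxylase of root suberin, rose 12.5-fold (3.65, SE 0.045), GPAT6, a glycerol-3-phosphate acyltransferase, 11.9-fold, and the transporter gene ABCG16 11.5-fold. CYP735A2, which makes trans-zeatin cytokinins, rose 9.91-fold and PMAT2 9.33-fold. Among genes with a symbol, the largest falls were in the subtilase gene ATSBT5.2 (24.6-fold, -4.62, SE 0.21, at -5.267 and -3.969 on its arrays), the transporter genes UMAMIT20 (21.9-fold) and UMAMIT17 (18.4-fold), XTH21 (18.3-fold), the peroxidase gene RCI3 (16.5-fold) and the transcription factor gene MYB68 (13.5-fold). GLYI4 fell 12.1-fold, DJ1F 11.4-fold, CASP5, a Casparian strip membrane protein, 9.22-fold, and CYP83A1, an enzyme of glucosinolate synthesis, 9.02-fold. The adjusted p of these 20 genes lay between 2.1e-06 and 4.9e-05. One locus without a symbol, chosen after its values were seen, rose more than any named gene: AT4G36430 was 127.4-fold higher (6.99, SE 0.176). The loci AT4G16270 (-5.17), AT3G01260 (-4.86) and AT5G43180 (-4.74), chosen in the same way, fell more than any named gene, the first from a probe above background in only some of these channels.

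Suberin genes rose together in the pair labelled ago1-101. All 13 tested members were higher (13 adjusted over the list alone), 11 of them at least 2-fold, with a median log2 fold change of 1.72 (adjusted p = 5.2e-10, and adjusted p = 0.51 with an estimated correlation). Beside CYP86A1, GPAT7 rose 6.38-fold, GPAT5 5.55-fold and FAR4 5.34-fold, all enzymes of suberin monomer synthesis. The list median was 1.72 on the first slide and 1.97 on the second. Of 22 root hair genes, 20 were higher, 0 lower and 2 not called (21 higher adjusted over the list alone), with a median of 0.80 (adjusted p = 8.8e-10, and adjusted p = 0.51 with an estimated correlation). RHS15 rose 5.85-fold, the expansin gene EXP18 2.81-fold, RHS19 2.65-fold and RHS18 2.44-fold.

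Vascular lists also rose. Of 16 phloem genes, 14 were higher and 2 not called (14 higher and 1 lower adjusted over the list alone), with a median of 1.03 (adjusted p = 1.8e-06), among them SEOR1 (2.63-fold) and PP2-A1 (2.50-fold), which encode sieve element and phloem proteins, SMXL4 (2.32-fold) and OPS (2.25-fold). Of 16 xylem genes, 14 were higher, 1 lower and 1 not called (14 and 1 adjusted over the list alone), with a median of 0.49 (adjusted p = 4.7e-05). The cellulose synthase genes of secondary walls CESA8 (1.77-fold) and CESA4 (1.48-fold), FLA11 (1.77-fold) and XCP1 (1.57-fold) were among them. With an estimated correlation, adjusted p = 0.51 for both vascular lists. The pericycle and procambium list fell: 8 of 9 members were lower and 1 higher (8 and 1 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.002, and adjusted p = 0.51 with an estimated correlation). SKOR, the potassium channel that loads the xylem, fell 8.57-fold and PHO1, the phosphate exporter of the stele, 2.68-fold. HKT1 fell 1.33-fold, and ATHB8, which is also a microRNA target, rose 1.96-fold.

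The SHORT-ROOT and SCARECROW pathway fell in the pair labelled ago1-101. Of 13 genes, 9 were lower, 2 higher and 2 not called (9 and 2 adjusted over the list alone), with a median of -0.45 (adjusted p = 6e-04, and adjusted p = 0.51 with an estimated correlation). Without SCR the median was -0.39 (adjusted p = 0.0024). The partners and direct targets SCL3 (2.76-fold), NUC (2.60-fold) and MGP (2.2-fold) were lower. Endodermis and Casparian strip genes went both ways, 5 higher, 5 lower and 2 not called (5 and 5 adjusted over the list alone, adjusted p = 0.52), with CASP5 lower and CASP4 1.91-fold higher. Its median of -0.02 became 0.09 without the first array of the pair.

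Among hormone and stress lists, cytokinin response genes were higher for 13 of 14 members with 1 not called (13 adjusted over the list alone), with a median of 0.57 (adjusted p = 3.3e-06). CKX3 (2.37-fold) and CKX6 (1.86-fold), which degrade cytokinins, and the response regulator genes ARR5 (1.86-fold) and ARR7 (1.73-fold) rose. All 8 tested defence genes were higher (8 adjusted over the list alone, median 0.66, adjusted p = 5.3e-05), led by WRKY53 (2.80-fold), RBOHD (2.75-fold), FRK1 (2.22-fold) and WRKY33 (1.64-fold). The other 6 of 14 members, PR1, PR2, PR5, CYP71A12, CYP71A13 and PDF1.2A, were not tested. All 6 root cap genes were higher (6 adjusted over the list alone, median 0.63, adjusted p = 0.00084), among them QRT1 (5.71-fold), CEL5 (1.69-fold), BRN1 (1.65-fold) and BRN2 (1.45-fold). With an estimated correlation, adjusted p = 0.51 for these 3 lists.

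Photosynthesis and shoot tissue, cell cycle, and abscisic acid and drought lists fell. Of 9 photosynthesis genes, 6 were lower and 3 not called (7 lower adjusted over the list alone), with a median of -0.92 (adjusted p = 0.00012, adjusted p = 0.52 with an estimated correlation, and adjusted p = 0.051 with fry). PSAD1 (3.27-fold), LHCA1 (2.23-fold), CHLH (2.11-fold) and GLK2 (1.90-fold) fell. Of 27 cell cycle genes, 15 were lower, 0 higher and 12 not called (18 lower adjusted over the list alone), with a median of -0.15 (adjusted p = 0.00042, and adjusted p = 0.51 with an estimated correlation). The changes were small, as in CYCD3;1 (log2 -0.32), CYCB1;4 (1.23-fold), CYCB1;1 (1.22-fold) and KNOLLE (1.21-fold), and the call ended with median centring (adjusted p = 0.18) and without the second array of the pair (adjusted p = 0.094). All 5 tested abscisic acid and drought genes were lower (5 adjusted over the list alone, median -0.40, adjusted p = 0.0094, and adjusted p = 0.51 with an estimated correlation), with HAI1 at 1.4-fold, RD29A at 1.32-fold, NCED3 at 1.2-fold and RAB18 at 1.42-fold. That call ended with fry (adjusted p = 0.097), with median centring (adjusted p = 0.12), without the dim filter (adjusted p = 0.095) and without the first array of the pair (adjusted p = 0.085).

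The other lists did not pass with camera in the pair labelled ago1-101. With fry, which tests members against 0 and not against the other genes, 5 of them passed: microRNA targets (adjusted p = 0.022) and auxin response and transport (0.032) higher, and small RNA machinery (0.032), endodermis and Casparian strip (0.032) and flavonoid synthesis (0.047) lower. On lists without AGO1 and SCR, an alternative chosen after the results were seen, the adjusted p with fry were, in that order, 0.02, 0.043, 0.19, 0.074 and 0.054. The direction of small RNA machinery with fry then turned from lower to higher. Of 84 microRNA targets, 31 were higher, 18 lower and 35 not called (33 and 19 adjusted over the list alone), with a median of 0.02 (adjusted p = 0.18). The members with the smallest p were LAC12, SULTR2;1 (8.23-fold higher), LAC13 (5.83-fold higher) and ATHB15 (2.16-fold higher). Small RNA machinery had 4 higher, 7 lower and 12 not called of 23 (4 and 7 adjusted over the list alone, adjusted p = 0.62), with RDR1 at 1.45-fold, AGO7 at 1.33-fold and HST at 1.28-fold higher and DCL1 1.21-fold lower. Cortex and root triterpenes had 5 higher, 3 lower and 2 not called of 10 (5 and 3 adjusted over the list alone, adjusted p = 0.58), among them C1 (2.27-fold lower), THAA (1.83-fold higher), THAS1 (1.58-fold higher) and CYP71A16 (1.54-fold lower). Epidermal patterning had 5 higher, 1 lower and 4 not called of 10 (6 and 2 adjusted over the list alone, adjusted p = 0.24), with ETC1 2.38-fold higher and MYB23 1.33-fold lower. The stem cell niche list had 2 higher, 3 lower and 4 not called of 9 (2 and 3 adjusted over the list alone, adjusted p = 0.52). WOX5, a marker of the quiescent centre, was 1.98-fold lower (-0.98, SE 0.117), from a probe above background in only some of these channels, and AGL42 was 1.37-fold higher. Auxin response and transport had 12 higher, 5 lower and 8 not called of 25 (12 and 7 adjusted over the list alone, adjusted p = 0.21), with IAA5 (3.69-fold), GH3.6 (2.37-fold), GH3.3 (2.18-fold) and IAA1 (1.69-fold) higher. Phosphate starvation had 3 higher, 3 lower and 3 not called of 9 (3 and 4 adjusted over the list alone, adjusted p = 0.84). Iron and copper had 4 higher, 3 lower and 4 not called of 11 (5 and 3 adjusted over the list alone, adjusted p = 0.98), with FER1 and NAS4 both at 1.85-fold, the first lower and the second higher. Flavonoid synthesis had 0 higher, 2 lower and 4 not called of 6 (5 lower adjusted over the list alone, adjusted p = 0.079), with F3'H 1.69-fold lower. Reference genes had 1 higher, 3 lower and 2 not called of 6 (1 and 3 adjusted over the list alone, adjusted p = 0.62). The test was lower while the mean was above 0 for small RNA machinery (median -0.03, mean 0.004), phosphate starvation (-0.07 and 0.02) and iron and copper (-0.05 and 0.001).

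In total, 9651 of 20025 genes passed in the pair labelled ago1-101, 5143 higher and 4508 lower, with a median size of 0.31 on the log2 scale. Of these, 620 were at least 2-fold higher and 422 at least 2-fold lower. On both arrays, 475 genes were at least 2-fold higher and 332 at least 2-fold lower, 807 in all, against 1600 with the deposited log ratios and 1237 from the first array alone. The count of calls fell to 5243 without the dye term and to 5141 with median centring. Of 23 lists, 12 passed, 7 higher and 5 lower, and 0 passed with an estimated correlation, where the lowest p without adjustment was 0.0883.

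The pair labelled scr-3 was compared with Col-0 in the same way. AGO1 had the largest fall of all tested genes. Among genes with a symbol, the cytochrome P450 genes CYP712A1 (AT2G42250) and CYP93D1 rose most, 87.6-fold (6.45, SE 0.063) and 73.6-fold (6.2, SE 0.071), and CYP712A2 rose 28.6-fold. The locus AT3G29410, chosen after its values were seen, rose by 6.31 on the log2 scale. HSD4 rose 46.1-fold, IRT1, the iron transporter of the root epidermis, 26.1-fold, ChlAKR 24.1-fold, PTAC18 21.4-fold and the homeobox gene HB53 20.2-fold. PXMT1 (23.5-fold) and TCP4 (22.2-fold) are known microRNA targets. ANNAT7, an annexin, fell 20.6-fold (-4.36, SE 0.043), the nitrate transporter gene NRT1.5 17.3-fold and SKOR 16.3-fold, and the last 2 load ions into the xylem. GSTF12 fell 12.8-fold, UMAMIT27 11.8-fold, the malate synthase gene MLS 9.90-fold, FLA6 9.72-fold, NAC080 9.62-fold and SQP2 9.09-fold. NAC080 is a known microRNA target as well. The adjusted p of the 10 rises and 10 falls lay between 6.8e-07 and 9.6e-06.

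MicroRNA targets were higher in the pair labelled scr-3. Of 84, 54 were higher, 15 lower and 15 not called (54 and 17 adjusted over the list alone), and 25 rose at least 2-fold, with a median of 0.49 (adjusted p = 1.4e-06, and adjusted p = 0.51 with an estimated correlation). SPL10 rose 15.5-fold (3.96, SE 0.040) and NFYA3 11.9-fold (3.57, SE 0.040). By the microRNA known to target them, all 9 tested SPL targets of miR156 were higher (median 1.56, 6 at least 2-fold), all 5 TCP targets of miR319 (median 1.63, 4 at least 2-fold) and all 5 class III homeobox targets of miR165 and miR166 (median 0.88). Of 7 NFYA targets of miR169, 5 were higher and 1 lower (median 1.49). AGL16, the target of miR824, had a log2 fold change of 2.83. Of 6 targets of miR164, 3 were higher and 3 lower (median -0.14). Of 2 targets of miR159, 0 were called, and of 3 targets of miR171, 0 were higher and 1 lower. Targets of miR172 had 4 of 6 lower, and of the 8 laccase and copper protein targets of miR397, miR408 and miR857, 5 were lower and 1 higher (median -0.49). In the pair labelled ago1-101, those 8 went the other way (7 higher and 1 lower, median 0.51), and the 5 homeobox targets were higher as well (median 0.99). These medians kept their direction with median centring, with scaling between arrays and with the deposited log ratios, where those of miR156, miR319 and miR169 targets were larger, at 2.75, 3.97 and 2.4. AGO1 is itself in this list. Without it the median in the pair labelled scr-3 was 0.50 (adjusted p = 3.8e-07).

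Small RNA machinery rose in the pair labelled scr-3, with 15 of 23 higher, 2 lower and 6 not called (15 and 2 adjusted over the list alone), a median of 0.24 (adjusted p = 0.0015, and adjusted p = 0.51 with an estimated correlation). AGO2 rose 5.73-fold (2.52, SE 0.041) and RDR1 3.81-fold. AGO3 rose 2.62-fold, from a probe above background in only some of these channels. The list call ended with median centring (adjusted p = 0.083).

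Iron and copper genes rose in the pair labelled scr-3. Of 11 genes, 10 were higher and 1 lower (10 and 1 adjusted over the list alone), and 7 rose at least 2-fold, with a median of 1.93 (adjusted p = 5e-06, and adjusted p = 0.51 with an estimated correlation). Beside IRT1, the ferric reductase gene FRO2 rose 15.4-fold, the regulator BHLH39 13.0-fold and NAS4, a nicotianamine synthase, 9.02-fold. FER1, the iron storage protein ferritin, was the member that fell.

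Suberin and root hair genes fell in the pair labelled scr-3. Of 13 suberin genes, 12 were lower and 1 not called (12 adjusted over the list alone), with a median of -1.34 (adjusted p = 2.9e-07, and adjusted p = 0.51 with an estimated correlation). GPAT7 fell 3.42-fold, FAR5 3.27-fold, CYP86B1 3.03-fold and ABCG2 2.82-fold, and the list median was -1.50 and -1.41 on the 2 slides. Of 22 root hair genes, 20 were lower and 2 not called (21 lower adjusted over the list alone), with a median of -0.75 (adjusted p = 2.5e-09, and adjusted p = 0.51 with an estimated correlation), among them PRP1 (5.45-fold), RHS15 (4.28-fold), RHS18 (3.54-fold) and RHS2 (2.60-fold). All 6 tested flavonoid synthesis genes were lower (6 adjusted over the list alone, median -1.18, adjusted p = 9.9e-05, and adjusted p = 0.51 with an estimated correlation), with F3H (2.61-fold), F3'H (2.48-fold), FLS1 (2.36-fold) and CHI (2.16-fold). Of 16 xylem genes, 11 were lower, 3 higher and 2 not called (12 and 3 adjusted over the list alone), with a median of -0.37 (adjusted p = 0.0096, and adjusted p = 0.79 with an estimated correlation), and this call ended with fry (adjusted p = 0.062). XND1 (2.11-fold), FLA11 (1.95-fold), CESA7 (1.81-fold) and CESA4 (1.78-fold) fell.

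Auxin, cell cycle and root cap lists rose in the pair labelled scr-3. Of 25 auxin response and transport genes, 15 were higher, 2 lower and 8 not called (15 and 2 adjusted over the list alone), with a median of 0.32 (adjusted p = 0.001, and adjusted p = 0.51 with an estimated correlation). GH3.3 rose 2.48-fold, LBD29 2.07-fold, IAA3 2.03-fold and the auxin efflux carrier gene PIN7 1.86-fold. Of 27 cell cycle genes, 18 were higher, 2 lower and 7 not called (18 and 2 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.0053, and adjusted p = 0.51 with an estimated correlation). CYCD3;3 rose 1.43-fold, TSO2 1.41-fold and CYCA1;1 1.28-fold, while CYCD3;1 fell 1.70-fold, and the call ended with median centring (adjusted p = 0.3) and without the first array of the pair (adjusted p = 0.06). Of 6 root cap genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.44 (adjusted p = 0.025, and adjusted p = 0.59 with an estimated correlation), a call that ended with the deposited log ratios (adjusted p = 0.071). CEL5 (2.02-fold), BRN2 (1.87-fold), FEZ (1.39-fold) and BRN1 (1.31-fold) rose.

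The other 13 lists did not pass in the pair labelled scr-3. The SHORT-ROOT and SCARECROW pathway had 3 higher, 5 lower and 5 not called of 13 (3 and 5 adjusted over the list alone, adjusted p = 0.71), with RLK (2.23-fold) and SCL3 (1.49-fold) higher and BLJ (1.89-fold) and MGP (1.42-fold) lower. Endodermis and Casparian strip had 4 higher, 2 lower and 6 not called of 12 (4 and 2 adjusted over the list alone, adjusted p = 0.59), and CASP5 was 5.43-fold lower. Cortex and root triterpenes had 3 higher, 6 lower and 1 not called of 10 (3 and 6 adjusted over the list alone, adjusted p = 0.51), with C1 4.35-fold higher and CYP705A5 2.03-fold lower. Phloem had 4 higher, 8 lower and 4 not called of 16 (4 and 8 adjusted over the list alone, adjusted p = 0.38), and PP2-A1 was 3.77-fold and SUC2 1.64-fold higher. Pericycle and procambium had 4 higher, 4 lower and 1 not called of 9 (4 and 4 adjusted over the list alone, adjusted p = 0.51). PHO1 was 2.46-fold lower, and HKT1, not above background in the mutant RNA, was at least 2.32-fold lower. Epidermal patterning had 4 higher, 5 lower and 1 not called of 10 (4 and 6 adjusted over the list alone, adjusted p = 0.57), with ETC1 3.68-fold higher and MYB23 2.55-fold lower. The stem cell niche list had 6 higher, 2 lower and 1 not called of 9 (6 and 2 adjusted over the list alone, adjusted p = 0.12), and AGL42 was 11.3-fold higher (3.5, SE 0.070).

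Cytokinin response had 3 higher, 6 lower and 5 not called of 14 in that pair (3 and 7 adjusted over the list alone, adjusted p = 0.14), and ARR16 was 6.13-fold and CKX5 1.77-fold lower. Phosphate starvation had 4 higher, 1 lower and 4 not called of 9 (4 and 2 adjusted over the list alone, adjusted p = 0.51), with PAP17 3.5-fold higher. Defence had 5 higher, 2 lower and 1 not called of 8 (5 and 2 adjusted over the list alone, adjusted p = 0.14), with MYB51 3.19-fold, FRK1 2.28-fold and RBOHD 1.90-fold higher. Abscisic acid and drought had 1 higher, 3 lower and 1 not called of 5 (1 and 3 adjusted over the list alone, adjusted p = 0.14), with RD29A 4.78-fold and NCED3 3.85-fold lower. Photosynthesis and shoot tissue had 1 higher, 5 lower and 3 not called of 9 (1 and 5 adjusted over the list alone, adjusted p = 0.1), with CHLH 2.27-fold and GLK2 2.0-fold lower. Reference genes had 2 higher, 1 lower and 3 not called of 6 (2 and 1 adjusted over the list alone, adjusted p = 0.99). Sign differed between median, mean and test for 5 of these lists: the SHORT-ROOT and SCARECROW pathway (median 0.03, mean -0.03, test lower), endodermis and Casparian strip (0.04, -0.12, higher), cortex and root triterpenes (-0.30, 0.02, lower), phosphate starvation (-0.02, 0.25, higher) and reference genes (-0.02, 0.003, lower).

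**Figure D2:**
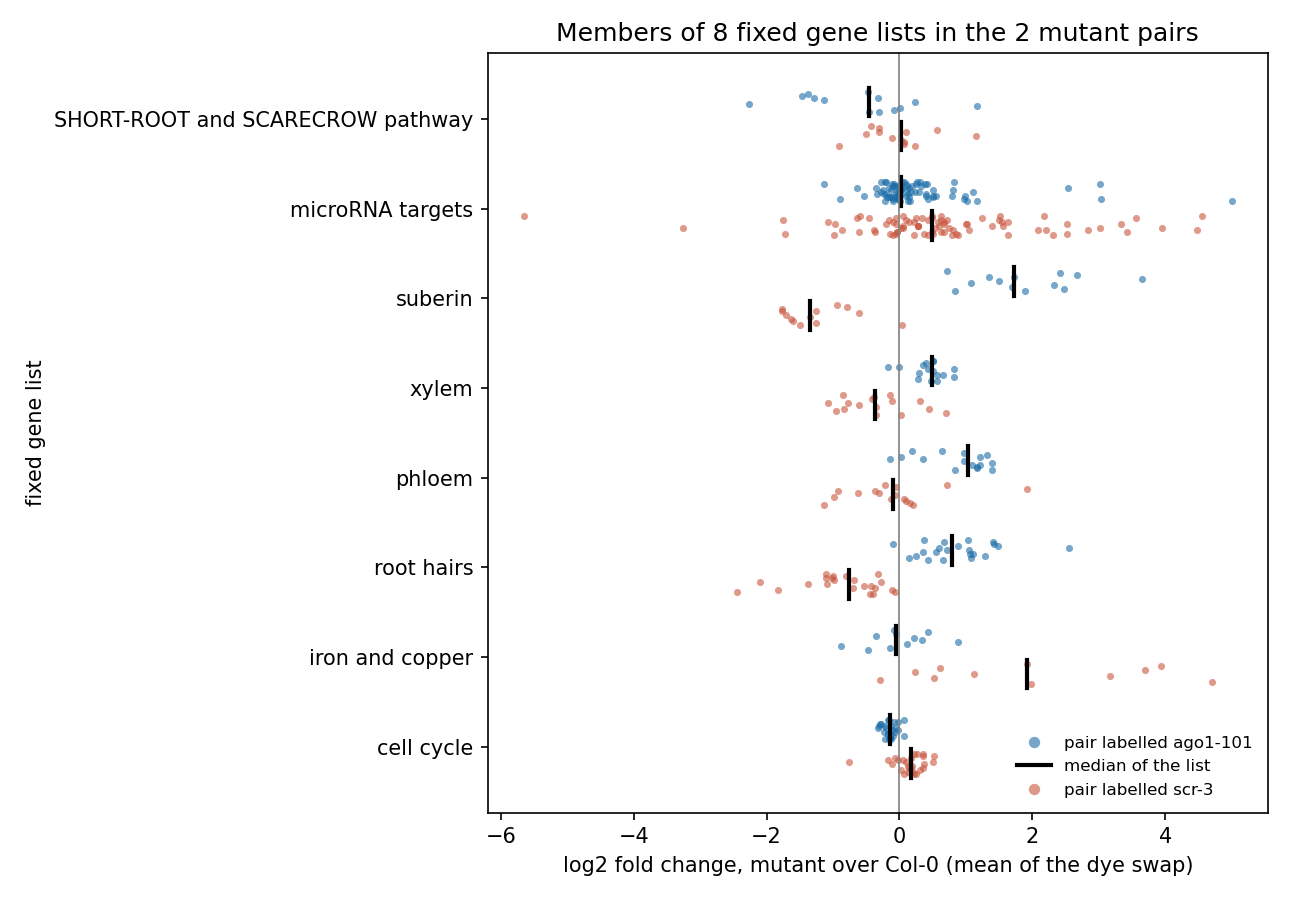
Log2 fold change of mutant over Col-0 (mean of 2 arrays) for the tested members of 8 gene lists, 1 point per gene, in the pair labelled ago1-101 and the pair labelled scr-3, with the list median as a black bar. The suberin medians lie at 1.72 and -1.34, and the microRNA target medians at 0.02 and 0.49.

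In total, 11309 of 20025 genes passed in the pair labelled scr-3, 5633 higher and 5676 lower, with a median size of 0.29 on the log2 scale. Of these, 461 were at least 2-fold higher and 558 at least 2-fold lower. On both arrays, 392 genes were at least 2-fold higher and 470 at least 2-fold lower, 862 in all, against 1494 with the deposited log ratios and 551 with median centring. The count of calls fell to 6122 without the dye term and to 5955 with median centring. Of 23 lists, 10 passed, 6 higher and 4 lower, and 0 passed with an estimated correlation, where the lowest p without adjustment was 0.0891.

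The 2 lines were then compared with each other through Col-0, since no array held both. Relative to the pair labelled scr-3, the pair labelled ago1-101 was higher in AGO1 (43.8-fold, 5.45, SE 0.057), FLA6 (30.5-fold), LAC12 (27.5-fold), RHS15 (25.1-fold) and LAC5 (24.0-fold). It was lower in CYP712A1 (53.3-fold, -5.74, SE 0.089), HSD4 (49.4-fold), ATSBT5.2 (30.0-fold, log2 -4.26 and -5.55 without the first and the second array of the pair labelled ago1-101) and IRT1 (28.7-fold). CYP93D1 was lower too, with a fitted difference of -5.86 (SE 0.101), but its Col-0 signal was not above background in the pair labelled ago1-101. In total 10891 genes differed, 5432 higher and 5459 lower in the pair labelled ago1-101, and 1806 of them at least 2-fold. The count was 5818 without the dye term and 5734 with median centring.

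Suberin genes differed most between the lines, with all 13 tested members higher in the pair labelled ago1-101 (13 adjusted over the list alone), a median difference of 3.21 and adjusted p = 1.3e-10. All 22 root hair genes were higher there (22 adjusted over the list alone, median 1.52, adjusted p = 5.1e-12). Flavonoid synthesis had 6 of 6 higher (6 adjusted over the list alone, median 0.96, adjusted p = 0.00042). With an estimated correlation, adjusted p = 0.56 for these 3 lists. Xylem had 12 of 16 higher, 2 lower and 2 not called (13 and 2 adjusted over the list alone, median 0.77, adjusted p = 1e-04, and adjusted p = 0.62 with an estimated correlation). Phloem had 13 of 16 higher, 1 lower and 2 not called (14 and 1 adjusted over the list alone, median 1.01, adjusted p = 5.6e-05, and adjusted p = 0.63 with an estimated correlation). Cytokinin response had 14 of 14 higher (14 adjusted over the list alone, median 0.77, adjusted p = 4.7e-06, and adjusted p = 0.62 with an estimated correlation), and fry did not call it (adjusted p = 0.053). Defence had 6 of 8 higher, 1 lower and 1 not called (6 and 1 adjusted over the list alone, median 0.54, adjusted p = 0.035, and adjusted p = 0.63 with an estimated correlation). The defence call ended with fry (adjusted p = 0.1), with median centring (adjusted p = 0.26), without the dye term (adjusted p = 0.058) and without any 1 of the 4 arrays (adjusted p = 0.054 to 0.13).

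Iron and copper genes were lower in the pair labelled ago1-101 than in the other, with 10 of 11 lower and 1 not called (10 adjusted over the list alone, median -2.01, adjusted p = 2.9e-06). MicroRNA targets had 50 of 84 lower, 21 higher and 13 not called (53 and 21 adjusted over the list alone, median -0.40, adjusted p = 0.00031), cell cycle 21 of 27 lower, 1 higher and 5 not called (22 and 1 adjusted over the list alone, median -0.35, adjusted p = 1e-04), small RNA machinery 12 of 23 lower, 2 higher and 9 not called (12 and 2 adjusted over the list alone, median -0.28, adjusted p = 0.0038), and the SHORT-ROOT and SCARECROW pathway 8 of 13 lower, 2 higher and 3 not called (8 and 2 adjusted over the list alone, median -0.53, adjusted p = 0.0056). With an estimated correlation, adjusted p = 0.56 for these 5 lists. With median centring, the cell cycle (adjusted p = 0.076) and small RNA machinery (adjusted p = 0.16) calls ended. The stem cell niche list had 7 of 9 lower and 2 not called (7 adjusted over the list alone, median -0.34, adjusted p = 0.021, and adjusted p = 0.63 with an estimated correlation), and fry did not call it (adjusted p = 0.1). The other 10 lists did not pass with camera, and 3 of them passed with fry: root cap higher (adjusted p = 0.033), and endodermis and Casparian strip (0.033) and auxin response and transport (0.04) lower. On lists without AGO1 and SCR, the fry call for endodermis and Casparian strip ended (adjusted p = 0.071). Adjusted p with camera was 0.34 for photosynthesis and shoot tissue, 0.35 for auxin response and transport, 0.38 for epidermal patterning, 0.41 for endodermis and Casparian strip, 0.42 for abscisic acid and drought, 0.67 for phosphate starvation, 0.74 for pericycle and procambium, 0.81 for cortex and root triterpenes, and 0.87 for root cap and for reference genes. Root cap (median -0.16, mean 0.40, test lower) and phosphate starvation (median 0.06, mean -0.22, test lower) differed in sign.

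Genes changed at least 2-fold on both arrays of both pairs overlapped more often than independent counts would give. Both pairs were lower in 92 genes (7.79 expected) and higher in 60 (9.3 expected), while 66 were higher in the pair labelled ago1-101 and lower in the other (11.1 expected) and 15 the reverse (6.5 expected). In the same order the counts were 168, 196, 150 and 48 with the deposited log ratios (25.6, 33.7, 36.4 and 23.7 expected), 56, 35, 28 and 5 with median centring (3.87, 4.11, 4.28 and 3.72 expected), and 108, 88, 86 and 24 without the second array of the pair labelled ago1-101 (11.3, 14.8, 17.7 and 9.42 expected), alternatives chosen after the results were seen. No test was applied to these overlaps, since genes are not independent and each array held Col-0 RNA that may be 1 extract. Shared falls included ANNAT7, SKOR, NRT1.5, XTH21, CASP5, UMAMIT20 and UMAMIT17, and AT4G36430 rose in both pairs (127.4-fold and 9.37-fold). Across all 20025 genes the mean log2 ratios of the 2 pairs had Pearson r = 0.125 and Spearman rho = 0.029. Between single arrays of the 2 pairs, r was 0.158 and 0.141 on the same slide and 0.102 and 0.072 on different slides. In 100 simulations with 1 shared Col-0 RNA and no mutant effect, the covariance was 0.00118, below the observed 0.0311. The simulated noise came from the residual spread between arrays. A deviation of 1 Col-0 extract that repeats on all arrays is not in that spread. The simulated covariance therefore does not bound what a shared extract adds. The simulated r was 0.499, which follows from its construction, since the simulated mutant and Col-0 noise had the same size. It is therefore no measure for the observed 0.125.

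**Figure D3:**
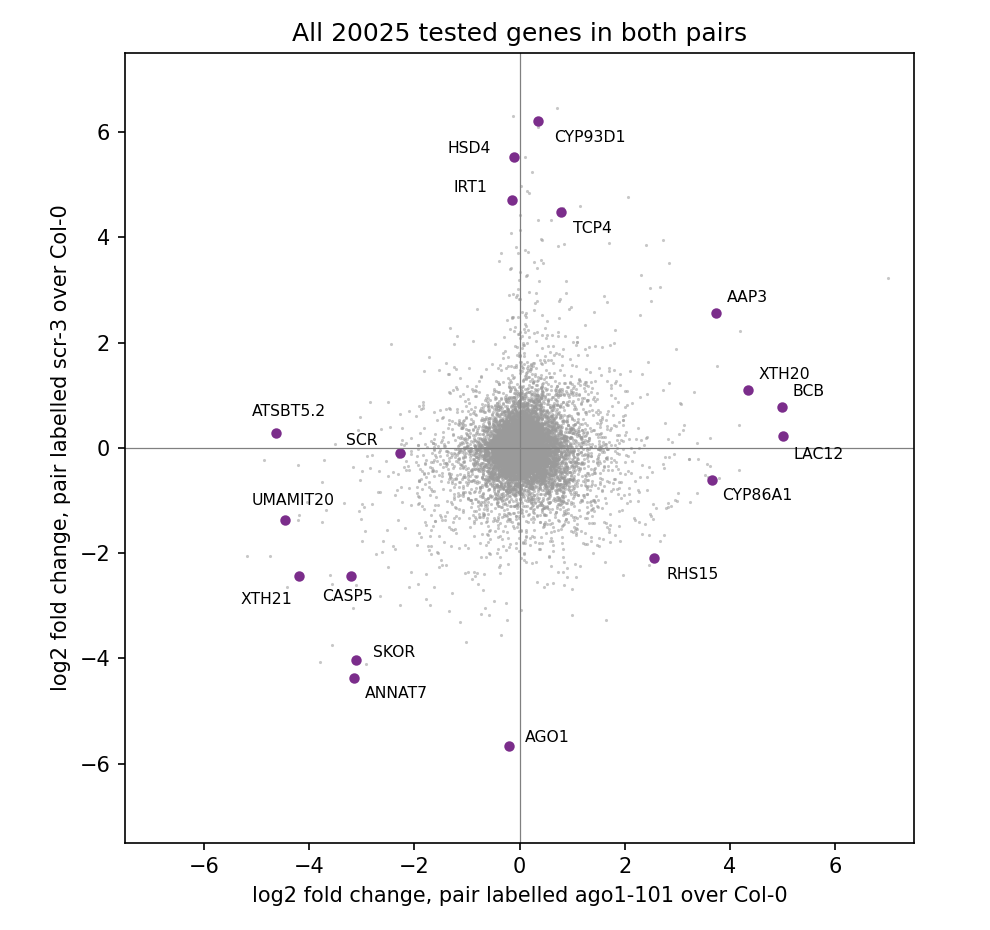
Log2 fold change over Col-0 of all 20025 tested genes in the pair labelled ago1-101 (horizontal axis) and the pair labelled scr-3 (vertical axis), 1 point per gene, with some genes named in purple. AGO1 lies at -0.21 and -5.66, SCR at -2.27 and -0.11, and Pearson r across genes is 0.125.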

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

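The tests of the labels, of the dye direction and of the loess normalisation were chosen only after the results they address were seen, as were the lists without AGO1 and SCR (with fry too), the medians by microRNA under other scalings and the spread of mature tissues without the endodermis list, while the test of a common share of mature tissue was written earlier.

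AGO1 and SCR differed between the pairs, by 5.45 (SE 0.057) and -2.16 (pair labelled ago1-101 minus pair labelled scr-3), and on 4 of 4 arrays the gene that was low was the one named on the other pair's label. A turned dye direction is argued against, because it would change the sign of AGO1 and SCR but not move the large change to the other pair, and the AGO1 change was larger by 5.45 in the pair labelled scr-3. An exchange of the mutant labels between the pairs is a candidate explanation. MicroRNA targets other than AGO1 lay lower in the pair labelled ago1-101 than in the other by a median of -0.4 (camera adjusted p = 0.00012). So did the SHORT-ROOT and SCARECROW pathway without SCR, by -0.47 (camera adjusted p = 0.019). With an estimated correlation, adjusted p was 0.56 for both whole lists. That form of camera rests on 1 residual degree of freedom and called 0 lists, so it does not decide here. The low AGO1 and SCR values under the other label, on 4 of 4 arrays, argue against the labels being right, but do not exclude it. Where the AGO1 probe lies relative to the insertion is not known, which bears only on AGO1 under its own label. The median of these microRNA targets in the pair labelled ago1-101, 0.02 (camera adjusted p = 0.14) with members going both ways, decides nothing. Fry, which tests members against 0, called them higher there (adjusted p = 0.02) as it did in the other pair (adjusted p = 0.017). If the labels are right, no value here accounts for AGO1 at -5.66 (SE 0.040) under the label scr-3. The same holds for medians of miR156 and miR319 targets of 1.56 and 1.63 in that pair against 0.15 and 0.01 in the other (the last -0.18 with the deposited log ratios). If the labels were exchanged, each statement on one pair would belong to the other line, and the sign of the difference would turn.

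Suberin, root hair and xylem genes were higher in the pair labelled ago1-101 and lower in the pair labelled scr-3, with median differences of 3.21, 1.52 and 0.77 (adjusted p = 0.56, 0.56 and 0.62 with an estimated correlation). One common change in the share of mature tissue was tested by the spread of the means of 6 lists of mature tissues within each pair (permutation p = 1e-05, the smallest that 100000 permutations can give). Without the endodermis list, which holds SCR, the other 5 means still ran from 0.06 to 1.87 in the pair labelled ago1-101 and from -1.24 to 0.02 in the pair labelled scr-3, with the same p. That test shuffled genes between lists as if they were independent, so its p does not decide. In the pair labelled ago1-101 the list medians on the 2 arrays were 1.72 and 1.97 for suberin and 0.43 and 0.45 for xylem. In the pair labelled scr-3 they were -1.5 and -1.41 for suberin and -0.45 and -0.3 for xylem. These values argue against a change that moves these 2 lists alike. The loess normalisation is argued against as the whole cause, since the suberin difference was 3.21 with median centring as well. A shift that moves tissues by unequal amounts stays open beside an effect of the mutations, and the cell cycle list ran opposite to the suberin, root hair and xylem lists in both pairs (medians -0.15 and 0.17).

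The cell cycle list differed in direction between the pairs as well, with a median difference of -0.35. With median centring its calls ended, at medians of -0.26 for the difference (adjusted p = 0.076), -0.13 in the pair labelled ago1-101 and 0.13 in the pair labelled scr-3, and the cause was not tested.

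Probes without a locus identifier were outside the comparisons and carried some signal. At least 2-fold changes on both arrays were found for 8 of 2095 probes named by position (0.382%) and 10 of 1308 named by a transcript accession (0.765%) in the pair labelled ago1-101, against 4.03% of genes. The counts in the pair labelled scr-3 were 13 (0.621%) and 14 (1.07%), against 4.3% of genes.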

How the results depend on the processing

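Lists without AGO1 and SCR, the targets of each microRNA under each scaling, fry on lists without those genes, an estimated correlation without the dye term, and the overlap of the pairs and neighbouring genes under each scaling and without each array, were chosen after the results were seen. The counts of called lists were 12, 10 and 13 with and without those genes.

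Of 221 called results on named genes, 216 kept their direction in every alternative where they were tested, and 175 stayed past the threshold in every one. All 127 results of at least 2-fold kept direction and call where they were tested. With the stricter filter on dim probes, 216 of 226 named gene results were tested. The largest rises and falls of each mutant were chosen for the same sign on both arrays, so leaving out 1 array could not turn their direction. All 35 called list results kept the direction of their median. AGO1 in the pair labelled scr-3 and SCR in the pair labelled ago1-101 kept direction and call in every alternative.

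The counts of called genes moved with several settings. Without the dye term they were 5243 (pair labelled ago1-101), 6122 (pair labelled scr-3) and 5818 (difference). With median centring they were 5141, 5955 and 5734, and the array medians of all tested genes then stood at 0.38, -0.315, 0.441 and -0.498. With scaling between arrays the count in the pair labelled scr-3 was 7215. With each mutant fitted alone the counts were 5040 and 7253. With the software's own p-value on both arrays they were 2979 and 2896. A 2-fold threshold in addition left 1042, 1019 and 1806, which follows from its construction. Leaving out 1 array in turn gave 4120 to 5116 in the pair labelled ago1-101, 3532 to 7253 in the pair labelled scr-3 and 4195 to 6002 for the difference. Here an arm with 1 array is assumed to vary like the others. These fits also drop the dye term, and 7253 and 6002 lie above the counts of 6122 and 5818 of all arrays without it. Apart from the 2-fold threshold, the cause was not tested.

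AGO1 in the pair labelled ago1-101 lost its call without the dye term (-0.21, adjusted p = 0.11), with the deposited log ratios and the series table (-0.27, adjusted p = 0.17 in both), with median centring (-0.17, adjusted p = 0.38) and with the mutant alone (-0.21, adjusted p = 0.16), and leaving out arrays gave -0.28 to -0.13. SCR in the pair labelled scr-3 passed without background correction (-0.11, adjusted p = 0.044), and leaving out arrays gave -0.25 to 0.04. The cause was not tested for either.

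Genes changed at least 2-fold on both arrays numbered 1600 and 1494 with the deposited log ratios and with the series table, and 551 in the pair labelled scr-3 with median centring. With 1 array left out, the count in the pair labelled ago1-101 was 883 to 1237. The correlation of the mutants was 0.17 with the deposited log ratios and with the series table, and 0.108 to 0.133 with 1 array left out. The cause was not tested. The number of called lists was 0, 0 and 0 with an estimated correlation in limma camera, and fry called 15, 9 and 13, of which 5, 0 and 3 were not called by camera and 10, 9 and 10 were. That form of camera rests on the 1 residual degree of freedom, and its lowest p without adjustment was 0.0785. Without the dye term as well, 4, 5 and 4 lists had a p under 0.05 without adjustment (lowest 0.017, 0.016 and 0.013), and the lowest adjusted p were 0.2, 0.15 and 0.17.

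Leaving out 1 array turned some directions. The endodermis and Casparian strip list in the pair labelled ago1-101 lay between -0.15 and 0.09. UBQ10 lay between -0.68 and 0.28 and EF1A between -1.02 and 0.6 in that pair, and in the pair labelled scr-3 ACT2 lay between -0.81 and 0.13, UBQ10 between -0.16 and 0.77 and EF1A between -0.48 and 0.9. These are the values of single arrays, without the exchange of dyes. A separate block for the slide was not run, since slide and dye orientation coincide. Signal over background limits what can be said of the 5412 dim loci, which were not tested.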

Other observations

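The grouping of genes into families by symbol, and the counts of neighbouring pairs under other settings, were chosen only after the results were seen, while the tests of a shared Col-0 RNA and of neighbouring genes were written earlier.

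Of 186 families with at least 8 tested loci whose symbols share a stem, 18 passed in the pair labelled ago1-101 and 4 in the pair labelled scr-3 with the preset correlation. With an estimated correlation 0 passed in either, and the lowest adjusted p was 0.95 and 0.99.

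The 92 genes lower in both pairs may share a cause in the Col-0 RNA, if both pairs were compared with 1 extract. Differences between the Col-0 channels of the 2 pairs had r = 0.139 between slides across 20025 genes, against 0.97 for the mutant channels. The value lies between those set in advance for 1 shared extract (under 0.1) and for separate extracts (over 0.5), so a shared Col-0 RNA cannot be told apart from separate ones. For the 92 genes the median difference between the Col-0 channels was 0.058 on the log2 scale, against 0.549 between the mutant channels. No test separated a shared Col-0 RNA from a common effect of both mutations.

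Genes that changed at least 2-fold on both arrays lay side by side more often than in random placements, which is consistent with neighbouring genes changing together. In the pair labelled ago1-101, 37 neighbouring pairs of 19911 placed genes changed in the same direction, against a mean of 16.8 and a highest count of 33 in 1000 placements. The count in the pair labelled scr-3 was 53, against a mean of 18.6 and a highest count of 36. The permutation p was 0.001 in both, the smallest that 1000 placements can give. The counts were 134 and 122 with the deposited log ratios (highest of random placements 92 and 79), 23 and 32 with median centring (19 and 18) and 58 and 40 with scaling between arrays (41 and 23), and the first was 89 without the second array of that pair (59). Among the latter were CYP93D1 beside CYP712A2, HSD4 beside HSD1, UMAMIT27 beside UMAMIT26, CYP706A1 beside CYP706A2 and GSTF7 beside GSTF6, pairs chosen after their values were seen. Several carry related names, and probes that bind the transcripts of both neighbours could give the same count, which was not tested.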
